A study of Homo sapiens with 10 samples.

How the data were processed

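SLAM-seq libraries from K562 cells were analysed from 3 deposited tables of read counts, with no further file. Per the file headers, the tables hold counts per gene of all human reads, of human reads that carry T-to-C conversions (labelled reads) and of Drosophila reads from the spike-in. The unit of every column is the raw count, not normalised, as deposited: all values were whole numbers, column totals differed between libraries, and no gene had more labelled than total counts in any library. Per the labels' protocols, RNA was treated with iodoacetamide, cleaned up, mixed with 5% Drosophila S2 RNA and made into QuantSeq 3′ mRNA libraries, a kit that reads from the poly(A) end of mRNA. The spike-in therefore scales each library to its amount of purified RNA and not to a number of cells, and a change in RNA per cell would not be seen. Per the submitters' processing notes, reads were handled with bcl2fastq 2.17.1.14, Trim Galore 0.6.5 and bedtools on the builds hg38 and dm6. The aligner, the caller of conversions and the filters on mapping are not given in the sources used here. Per the labels' protocols no labelling of the spike-in is described, so it scales labelled and total counts alike.

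The human tables list 59204 genes, and 17509 genes are listed for the spike-in. Symbols, gene types and positions came from GENCODE release 29, which held 55838 of the human identifiers. Total human counts per library ran from 14916671 to 17918971 and spike-in counts from 1817677 to 2212752, which was 10.0 to 11.7% of each library. All 10 libraries and all columns of values were used. Intervals on shares are 95% Wilson intervals, and a group with no counts was given an upper limit of 3 counts over the group. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

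Groups were taken from the sample titles, with 2 libraries each for DMSO, actinomycin D, AZ-5576, JQ1 and A-485. Each drug was compared with DMSO in labelled RNA, in total RNA and in the labelled share of each gene, and neighbouring drugs were compared with each other in labelled RNA. Tests used edgeR 4.0.16 (quasi-likelihood, robust, two-sided) in R 4.3.3, with the spike-in total as library size, all 10 libraries in one fit, genes with at least 10 counts in at least 2 libraries, and Benjamini-Hochberg adjusted p under 0.05. This left 7996 genes in labelled RNA, 14572 in total RNA and 7960 for the share, each fit with 5 residual degrees of freedom. The common biological coefficient of variation was 24.8% in labelled RNA, 10.9% in total RNA and 17.8% for the share. A permutation of 2 libraries against 2 can give no two-sided p below 0.33, so library-wide measures are given with their SD and no p. The test of the share fitted labelled and unlabelled counts of each library together, with the drug effect on their ratio.

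Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), and again with a correlation estimated from the residuals. Adjusted p of lists are Benjamini-Hochberg over the 23 lists of a comparison. The lists were immediate early and short-lived mRNAs, erythroid and megakaryocytic transcription factors, globin, heme and erythroid membrane genes, cytosolic ribosomal proteins, glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded genes, the proteasome, pause release and BET proteins, RNA polymerase II with Mediator and acetyltransferases, mRNA decay factors, apoptosis regulators, p53 targets, MYC targets with ribosome biogenesis, G2 and mitosis, S phase, replication-dependent histones, heat shock, the unfolded protein and integrated stress response, cholesterol synthesis, NF-kB and inflammation, interferon response, and markers of lymphoid, myeloid and non-blood lineages. Named genes followed a rule. It took a panel (MYC, MYB, GATA1, TAL1, LMO2, KLF1, NFE2, HEXIM1, BRD2, MCL1, BCL2L1, JUN, IER2, CDK9, TFRC, HBG1, GAPDH and ACTB), the largest changes among genes with a mean of at least 50 counts whose libraries did not overlap, and the called members of each list with the highest counts. These were labelled counts, or total counts for changes in total RNA, in whichever group compared had the higher mean. Results of 3 genes are not reported here. The lists, the naming rule, the tests and all alternatives except the ones named as later additions were fixed before the data were examined.

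For the relation between total RNA and turnover, 10409 genes with at least 50 total counts per DMSO library on average were placed in 5 bins by their labelled share in DMSO. Similarity between drugs was compared with 20 simulated sets in which the drugs shared the DMSO libraries and nothing else. The fits were tested on data simulated for A-485 against DMSO alone: with 100 genes changed at each fold size, the labelled fit recovered 21% of 2-fold and 65% of 4-fold changes, the total fit 73% and 94%, and the share fit 15% and 73%. Between 4 and 5 unchanged genes were called in each of these simulations. Their counts were drawn with the spread estimated by the fits, the other groups at DMSO levels and no structure shared between libraries. The real libraries may therefore give more false calls and recover less. Alternatives were TMM factors from the human counts, which aim to set the typical gene to no change, TMM factors of the total table and spike-in factors by the median of ratios. Others were DESeq2 1.42.0, limma on log ratios for the share, and filters at no minimum and at 50 counts. Fits of 2 groups alone, a replicate term and leaving out each library in turn were also used. Later additions, chosen after seeing the data, were a term for the replicate 2 libraries of the 4 drugs, fits without processed pseudogenes, and library-wide measures without mitochondrial genes. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.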

Results

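K562, a human chronic myeloid leukemia line with erythroid and megakaryocytic features, was treated for 2 hours with DMSO or with 1 of 4 drugs that act on transcription by RNA polymerase II, and 100 µM 4-thiouridine was present in the final 1 hour. Actinomycin D (1 µg/mL) binds DNA and stops elongating polymerases, and AZ-5576 (1 µM) inhibits CDK9, the kinase that releases paused polymerase. JQ1 (1 µM) displaces BET bromodomain proteins from acetylated chromatin, and A-485 (1 µM) inhibits the acetyltransferases CBP and p300. 4-thiouridine enters new RNA and is read as T-to-C conversions, so labelled reads count RNA made in the label hour and all reads count the mRNA pool. Each of the 5 groups held 2 libraries. Total human counts per library ran from 14916671 to 17918971. Labelled counts were 448401 and 434411 in DMSO, 1410 and 1614 with actinomycin D, 53503 and 62513 with AZ-5576, 342847 and 322771 with JQ1, and 411716 and 447455 with A-485.

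The first question was how far each drug lowered new RNA as a whole. Labelled human counts per 1000 spike-in counts were 238 ± 1.72 in DMSO (SD, n = 2), 0.721 ± 0.0291 with actinomycin D, 29.8 ± 0.765 with AZ-5576, 154 ± 1.54 with JQ1 and 217 ± 11.7 with A-485. These were 0.303%, 12.5%, 64.7% and 91.4% of the DMSO level in that order, and the libraries of each drug lay below both DMSO libraries. Mitochondrial RNA, which is made by a separate polymerase inside the organelle, behaved apart under AZ-5576. Labelled RNA of mitochondrial genes and their nuclear copies stayed at 74.5% of DMSO, and the rest fell to 6.19%. With JQ1 the 2 classes stood at 82.4% and 62.9%, with A-485 at 88.9% and 91.6%, and with actinomycin D both were under 1%, at 0.353% for mitochondrial RNA. Labelled reads made up 2.78% ± 0.165 of human counts in DMSO, 0.00906% ± 6.8e-05 with actinomycin D, 0.356% ± 0.00434 with AZ-5576, 1.97% ± 0.110 with JQ1 and 2.58% ± 0.113 with A-485. The mRNA pool moved little beside this: total human counts per spike-in count were 8.59 ± 0.571 in DMSO, and the means of the drugs were 92.7%, 97.7%, 91.1% and 98.1% of it. The spike-in was added to purified RNA, so these values are per amount of RNA and not per cell.

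**Figure D1:**
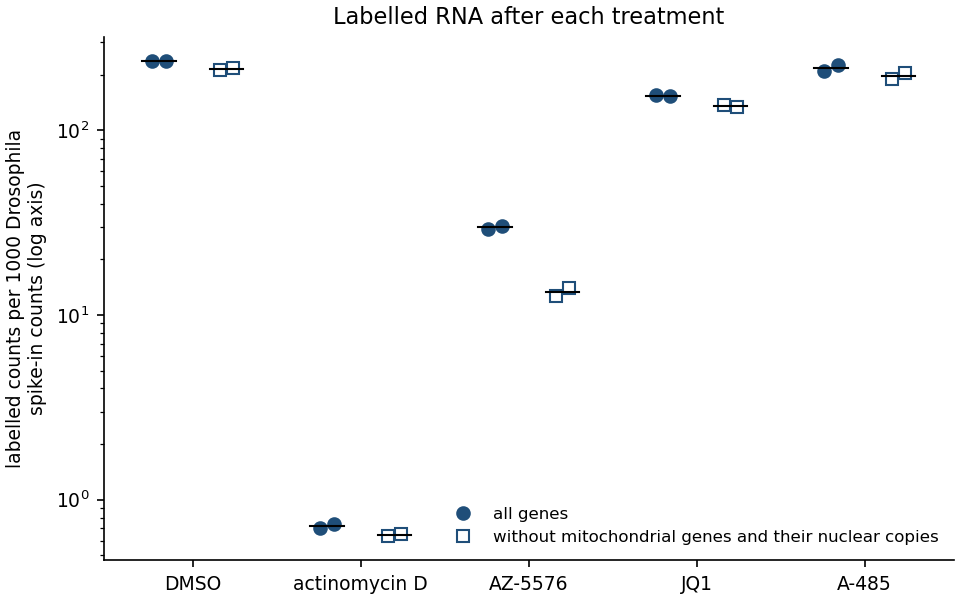
Labelled human counts per 1000 spike-in counts on a log axis for each library (points) and group mean (lines), for all genes (filled) and without mitochondrial genes and their nuclear copies (open), with DMSO at 238 and actinomycin D at 0.721. The 4 drugs line up as actinomycin D, AZ-5576, JQ1 and A-485 from the lowest to the highest level.

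Actinomycin D against DMSO asked what is left when elongation stops on all templates. New RNA was lost from nearly every gene measured. PRAME, a tumor antigen, went from 1697 and 1814 labelled counts to 0 and 0, at least 1321-fold lower by the limit of 3 counts over the group. BRD2, a BET protein, was at least 587-fold lower, NFE2, an erythroid transcription factor, at least 195-fold lower, TFRC, the transferrin receptor, at least 194-fold lower, and MYC at least 81.6-fold lower (n = 2 each). MYC (ENSG00000136997) lies on hg38 chromosome 8 from 127735434 to 127741434. In all, 7933 of 7996 genes fell and 0 rose (edgeR, 0 higher at an unadjusted p under 0.05, 0 with DESeq2). On the TMM scale, which moved genes up by a median of 0.93, 25 rose and 2268 fell. All measured members fell in 18 of the lists, over all genes and adjusted over the list alone, among them 76 of 76 ribosomal protein genes, 63 of 63 respiratory chain genes, 47 of 47 MYC targets, 56 of 56 mRNA decay factors, 31 of 31 proteasome genes and 11 of 11 mitochondrially encoded genes. The exceptions were 34 of 35 immediate early genes, 41 of 42 G2 and mitosis genes, 11 of 12 histone genes (on the TMM scale 1 higher and none lower), 22 of 23 cholesterol genes and 4 of 5 lineage markers. With labelled counts at or near 0, how far a gene or list fell beyond others is set by its DMSO counts, so differences between lists are not read from this comparison.

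Total RNA after 2 hours of actinomycin D showed which mRNAs had already run down. Immediate early and short-lived mRNAs fell most clearly, in 32 of 39 measured (34 adjusted over the list alone; camera adjusted p = 0.00974 with an estimated correlation). JUN fell by 2.28 on the log2 scale (SE 0.23, n = 2, adjusted p = 9.5e-10), MYC fell by 1.82 (SE 0.19), IER2 fell by 1.26 (SE 0.13) and MCL1, a short-lived survival factor, fell by 1.18 (SE 0.11). NFKBIA, the inhibitor of NF-kB, fell by 3.00 (SE 0.25). Erythroid regulators fell in 17 of 28 (19 adjusted over the list alone), a set call lost at adjusted p = 0.421 with an estimated correlation. Among them ZBTB7A fell by 1.38 (SE 0.11), GATA2 fell by 0.96 (SE 0.11) and NFE2 fell by 0.88 (SE 0.11). HBG1, a fetal globin, stood at -0.01 (SE 0.11), GAPDH at 0.03 (SE 0.10) and ACTB at -0.04 (SE 0.10) and did not pass the test, while on the TMM scale they stood at 0.25, 0.29 and 0.21, with GAPDH called. Mitochondrially encoded mRNAs split, with 6 of 12 lower and 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.00974 with an estimated correlation). MT-ND1 fell by 2.87 (SE 0.11) and MT-CYB fell by 1.40 (SE 0.09), while MT-CO1 rose by 0.93 (SE 0.12) and MT-ND5 by 0.60 (SE 0.11), the last 2 named after their values were seen.

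Among the other lists in total RNA with actinomycin D, 13 of 25 p53 targets fell (15 adjusted over the list alone), where AEN, a nuclease, fell by 0.77 (SE 0.11), and 13 of 25 genes of the integrated stress response (18), where SLC3A2, an amino acid transporter subunit, fell by 1.03 (SE 0.12). There were falls in 21 of 50 MYC targets (22 adjusted over the list alone), 23 of 62 decay factors (25), 16 of 50 polymerase and Mediator genes (19), 12 of 29 pause release genes (14), 10 of 45 S phase genes (17), 10 of 45 mitosis genes (10), 8 of 20 NF-kB genes (9) and 8 of 26 apoptosis regulators (9). TAF1D, a factor for RNA polymerase I, fell by 1.51 (SE 0.11), HEXIM1, which holds CDK9 inactive, fell by 0.71 (SE 0.13), EP300 fell by 0.71 (SE 0.12), and DNAJB1, a heat shock cochaperone, fell by 1.21 (SE 0.12). Few members fell among proteasome, heat shock and cholesterol genes, with 3 each (1, 3 and 3 adjusted over the list alone). A single member fell among globin and heme genes, ribosomal proteins, glycolysis, respiratory chain, histones and interferon genes (0, 1, 1, 0, 1 and 1), and 0 of 16 lineage markers changed over all genes and over the list alone (edgeR). No set test of these lists held with an estimated correlation, where the lowest was adjusted p = 0.0825 for the stress response. Across 14572 genes 2874 fell and 49 rose. On the TMM scale, which moved genes up by a median of 0.26, 1142 fell and 836 rose. There 57 of 78 ribosomal protein genes, 37 of 67 respiratory chain genes, 9 of 31 proteasome genes, 8 of 38 globin and heme genes, 6 of 19 glycolysis genes and 3 of 16 lineage markers were higher and none lower, mitosis genes turned to 4 higher and 1 lower, heat shock genes to 6 and 3, and MYC targets stood at 6 and 7. The falls numbered 1205 without DMSO replicate 2, 1708 without actinomycin D replicate 1 and 1877 without replicate 2, and the rises 32 without DMSO replicate 2 and 27 without actinomycin D replicate 2. Of the 49 rises, 26 were processed pseudogenes, whose reads may be shared with near-identical parent genes, so these are uncertain.

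AZ-5576 against DMSO asked the same of CDK9. New RNA of nuclear genes was largely lost, by a finite amount for most genes named here. MYC fell by 3.81 on the log2 scale (SE 0.48, n = 2, adjusted p = 1.3e-14), with 7 and 9 labelled counts against 109 and 108. BRD2 fell by 4.31 (SE 0.21) and NFE2 fell by 4.36 (SE 0.36), the latter standing at -5.15 without AZ-5576 replicate 1. ACTB fell by 4.05 (SE 0.28), GAPDH fell by 5.65 (SE 0.35) and HSPA8, a constitutive chaperone, fell by 4.90 (SE 0.21). HEXIM1 went to 0 and 0 counts, at least 47.8-fold lower, and TOMM5, a mitochondrial import protein, likewise to at least 280-fold lower. GATA2 fell by 1.93 (SE 0.23) on the spike-in scale but stood 1.23 higher on the TMM scale, where the median gene still stood at -3.43. MT-CYB fell by 0.49 (SE 0.13) and MT-ATP6 fell by 0.70 (SE 0.15), and on the TMM scale they stood 2.67 and 2.46 higher. In all, 7574 of 7996 genes fell and 16 rose, against 3111 and 392 on the TMM scale, which moved genes up by a median of 2.91. The 16 rises became 7 without AZ-5576 replicate 1 and 5 without replicate 2.

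By group, the labelled RNA of 76 of 76 ribosomal protein genes, 63 of 63 respiratory chain genes, 56 of 56 decay factors, 47 of 47 MYC targets, 42 of 42 mitosis genes, 31 of 31 proteasome genes, 25 of 25 pause release genes, 24 of 24 heat shock genes and 22 of 22 stress response genes fell under AZ-5576, as did 17 of 17 in glycolysis, apoptosis and p53 targets and 13 of 13 NF-kB genes. The same counts held when adjusted over the list alone. Not every member was called in immediate early genes (34 of 35), polymerase and Mediator genes (42 of 43), S phase (41 of 42), globin and heme genes (19 of 20), erythroid regulators (20 of 23), cholesterol genes (20 of 23), histones (11 of 12) and interferon genes (3 of 4), and these counts too were the same over the list alone. Over all genes measured 94.7% were lower, so a few members not called are not read as a trait of these lists. On the TMM scale the falls were fewer, with 29 lower and 4 higher among ribosomal proteins, 8 and 4 among erythroid regulators, 9 and 1 among globin and heme genes and 5 and 2 among cholesterol genes. Of 5 lineage markers 4 fell and 1 rose, the same over the list alone. Mitochondrially encoded genes were the clear exception, with 6 of 11 lower on the spike-in scale (5 adjusted over the list alone), but 10 of 11 higher and none lower on the TMM scale. Their median was -0.47 while camera placed them above other genes, a call lost at adjusted p = 0.110 with an estimated correlation. No list held with an estimated correlation under AZ-5576, the lowest being adjusted p = 0.0705 for ribosomal proteins.

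In total RNA the falls with AZ-5576 again centred on immediate early and short-lived mRNAs, 34 of 39 lower (35 adjusted over the list alone; adjusted p = 0.00526 with an estimated correlation). JUN fell by 2.33 (SE 0.23, n = 2, adjusted p = 9.8e-10), MYC fell by 1.48 (SE 0.19). MCL1 fell by 1.18 (SE 0.11), BRD2 fell by 1.27 (SE 0.10) and MIR17HG, the host gene of the miR-17 cluster, fell by 4.16 (SE 0.18). ATF4, the main factor of the integrated stress response, fell by 0.99 (SE 0.12), NFKBIA fell by 3.06 (SE 0.26) and IRF1 fell by 2.37 (SE 0.29). Erythroid regulators fell in 12 of 28 and rose in 1 (12 and 1 adjusted over the list alone), where ZBTB7A fell by 1.30 (SE 0.11) and NFE2 fell by 0.77 (SE 0.11), lost as a set at adjusted p = 0.405 with an estimated correlation. Falls also reached 13 of 25 stress response genes (13 over the list alone), 12 of 25 p53 targets (13), 8 of 20 NF-kB genes (8), 19 of 62 decay factors (22), 16 of 50 MYC targets (17), 14 of 50 polymerase and Mediator genes (15, with 1 higher), 10 of 45 S phase genes (13), 8 of 29 pause release genes (9), 7 of 26 apoptosis regulators (10), 6 of 25 cholesterol genes (6) and 5 of 45 mitosis genes (5), where 12.9% of all genes were lower. No list but the immediate early one held with an estimated correlation, and adjusted p was 0.0776 for p53 targets, 0.140 for NF-kB and 0.405 each for decay factors, pause release and apoptosis. Lists with at most 2 members lower were interferon (2, also 2 over the list alone), heat shock (2 and 2, with 1 and 0 higher), histones (1 and 0), proteasome (1 and 0), respiratory chain (1 and 0) and globin and heme (1 and 1, with 1 and 1 higher). Ribosomal proteins, glycolysis and mitochondrially encoded genes had 0 called over all genes and over the list alone (edgeR), although 34 of 78 ribosomal protein genes and 7 of 12 mitochondrially encoded genes were higher on the TMM scale. On that scale 12 respiratory chain genes, 3 proteasome genes, 1 glycolysis gene and 1 histone gene were higher and none lower, globin and heme genes turned to 7 higher and 1 lower, and polymerase and Mediator genes stood at 6 and 6. DCN, a matrix proteoglycan of connective tissue, was the only one of 16 lineage markers called, at 25 and 15 counts against 1 and 1, and was lost without either DMSO library or without AZ-5576 replicate 1 (adjusted p = 0.0769, 0.104 and 0.0851 in that order). Across all genes 1878 fell and 114 rose, against 1210 and 517 on the TMM scale, which moved genes up by a median of 0.15. Falls numbered 903 without DMSO replicate 2 and 1036 without AZ-5576 replicate 1, and rises 44 and 65 without DMSO replicates 1 and 2, and 68 and 48 without AZ-5576 replicates 1 and 2. Of the 114 rises 19 were processed pseudogenes, uncertain as above.

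**Figure D2:**
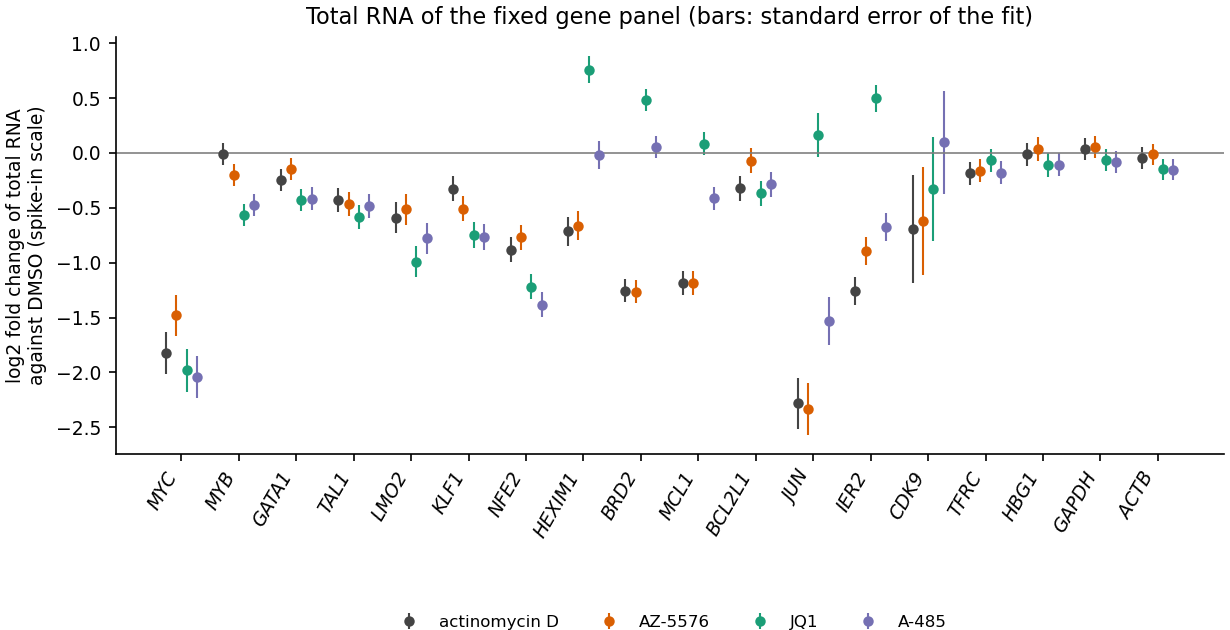
Log2 change in total RNA against DMSO for the panel genes under each drug, with bars for the SE of the fit (n = 2 libraries per group). MYC lies between -1.48 and -2.04 with all 4 drugs, while HEXIM1 is lower with actinomycin D and AZ-5576 and higher with JQ1.

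JQ1 against DMSO asked which genes depend on BET proteins. New RNA of most erythroid regulators fell and labelled reads of replication-dependent histones rose. The kit reads from the poly(A) end, so histone mRNA without a poly(A) end would not be counted, here and in total RNA. NFE2 fell by 3.21 on the log2 scale (SE 0.31, n = 2, adjusted p = 1.7e-21), MYB fell by 3.19 (SE 0.47). LMO2 fell by 3.54 (SE 0.58), KLF1 fell by 2.94 (SE 0.59), TAL1 fell by 2.51 (SE 0.45) and MYC fell by 2.46 (SE 0.41). The size for MYC is uncertain, with 40 and 6 labelled counts under JQ1, and stood at -4.33 without JQ1 replicate 1 and -1.69 without replicate 2. Without JQ1 replicate 1 MYB stood at -3.84, and without replicate 2 KLF1 stood at -3.73. HBG1 fell by 2.71 (SE 0.21) and HBG2 fell by 3.38 (SE 0.22), fetal globin genes so alike that reads may be shared between them. Erythroid regulators fell in 18 of 23 (18 adjusted over the list alone; on the TMM scale 13, with 1 higher), a set call lost at adjusted p = 0.0613 with an estimated correlation, and globin, heme and membrane genes in 11 of 20 (11 lower and 1 higher over the list alone; 7 lower and 4 higher on the TMM scale; adjusted p = 0.1498 with an estimated correlation), and ANK1, the membrane ankyrin, fell by 1.70 (SE 0.25). STAR, a cholesterol transporter, went from 84 and 87 labelled counts to 1 and 2. In the other direction, 9 of 12 histone genes rose (10 adjusted over the list alone; adjusted p = 0.00331 with an estimated correlation, the list with the lowest value), with H3C10 up by 1.74 (SE 0.37), H2AC6 by 1.60 (SE 0.39) and H2BC5 by 2.12 (SE 0.44). H3C10 stood at 2.34 without DMSO replicate 2 and H2BC5 at 2.82 without DMSO replicate 1. H4C15 rose by 4.35 (SE 0.55) and H4C14 by 3.82 (SE 0.54), copies with the same coding product that may share reads. HEXIM1 (hg38 chromosome 17, from 45148502 to 45152101) rose by 1.52 (SE 0.29) and POLR2A, the largest subunit of RNA polymerase II, by 1.32 (SE 0.34).

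On the spike-in scale 28.6% of all genes measured in labelled RNA were lower with JQ1, so a list with a similar part lower is not read as a response of its own. TMM scaling moved genes up by a median of 0.77. Of 47 MYC targets 31 fell (32 adjusted over the list alone; 8 on the TMM scale, with 2 higher), where PA2G4 fell by 1.53 (SE 0.22) and WDR43 fell by 1.48 (SE 0.22), and of 76 ribosomal protein genes 46 fell (49; on the TMM scale 7 fell and 8 rose, with a median of 0.04 in place of -0.74). Falls covered 30 of 63 respiratory chain genes (33; 3 on the TMM scale, with 1 higher), 22 of 56 decay factors with 1 higher (28 and 1; 5, with 2 higher), 16 of 31 proteasome genes (19; 1, with 1 higher), 14 of 43 polymerase and Mediator genes with 1 higher (17 and 1; 1, with 2 higher), 12 of 42 mitosis genes (12; 1, with 7 higher), 12 of 42 S phase genes with 1 higher (15 and 1; 3, with 5 higher), 6 of 17 glycolysis genes (9; 1, with 2 higher) and 2 of 11 mitochondrially encoded genes (2; 0, with 6 higher). The set calls of MYC targets, ribosomal proteins and respiratory chain were each lost at adjusted p = 0.1498 with an estimated correlation. Falls in other lists reached 4 of 17 p53 targets (4 over the list alone), where AEN fell by 2.15 (SE 0.27), 4 of 17 apoptosis regulators (4), where BCL2L1 fell by 2.64 (SE 0.51), 4 of 13 NF-kB genes (4), where CXCL3 fell by 3.59 (SE 0.60) and stood at -4.40 without JQ1 replicate 1, 4 of 25 pause release genes with 1 higher (4 and 1; on the TMM scale none lower and 4 higher), and 5 of 22 stress response genes with 1 higher (4 and 1; on the TMM scale 1 lower and 5 higher). On the TMM scale p53 targets stood at 1 lower and 1 higher, apoptosis regulators at 3 and 2, and NF-kB genes at 2 and 0. On the spike-in scale immediate early genes split, 4 higher and 4 lower of 35 (4 and 4), with IER5 up by 0.97 (SE 0.21). Heat shock genes split, 4 higher and 5 lower of 24 (4 and 5), where HSPB1 fell by 1.82 (SE 0.21), and cholesterol genes split, 2 higher and 3 lower of 23 (1 and 0). On the TMM scale these 3 lists leaned up, with 10 higher and 3 lower, 10 and 1, and 4 and 0. For these 3 lists camera pointed up while the medians were -0.03, -0.08 and 0.00, and the calls were lost at adjusted p = 0.0906, 0.153 and 0.0613 with an estimated correlation. Of 4 interferon genes IRF7 alone rose (1 over the list alone), by 3.61 (SE 0.91), which was lost without DMSO replicate 1 (3.02, adjusted p = 0.0538) and stood at 4.56 without DMSO replicate 2, and of 5 lineage markers 1 rose and 2 fell (1 and 2). In all 2286 genes fell and 101 rose, against 471 and 401 on the TMM scale and 1550 and 133 with TMM factors of the total table. Falls numbered 1143 and 1049 without DMSO replicates 1 and 2, and rises 51 without either DMSO library and 56 and 61 without JQ1 replicates 1 and 2.

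In total RNA with JQ1, 16 of 28 erythroid regulators fell (18 adjusted over the list alone), a set call lost at adjusted p = 0.191 with an estimated correlation, and 10 of 19 histone genes rose (12 over the list alone; adjusted p = 0.00585 with an estimated correlation). NFE2 fell by 1.22 (SE 0.11, n = 2, adjusted p = 6.4e-10), MYC fell by 1.98 (SE 0.19). LMO2 fell by 0.99 (SE 0.14), GATA2 fell by 0.83 (SE 0.10) and MYB fell by 0.56 (SE 0.10), while H3C10 rose by 0.75 (SE 0.13). HEXIM1 rose by 0.76 (SE 0.13) and BRD2 by 0.48 (SE 0.10). Of 29 pause release genes 3 were lower and 2 higher (3 and 2). Immediate early genes rose in 7 and fell in 3 of 39 (8 and 7; adjusted p = 0.505 with an estimated correlation, with a median of -0.08 though the test pointed up), with IER5 up by 1.17 (SE 0.11) and JUNB by 1.00 (SE 0.14). There were falls in 18 of 50 MYC targets (22; on the TMM scale 3, with 1 higher), 13 of 62 decay factors with 1 higher (17 and 1; 7 and 1 on the TMM scale), 6 of 20 NF-kB genes (8), 5 of 50 polymerase and Mediator genes (6), 4 of 45 S phase genes (5), 4 of 25 stress response genes with 1 higher (5 and 3), 3 of 25 p53 targets (4, with 1 higher) and 3 of 26 apoptosis regulators (6). The set calls of MYC targets, NF-kB genes and decay factors were lost at adjusted p = 0.505, 0.494 and 0.936 with an estimated correlation. Heat shock genes rose in 3 and fell in 1 of 27 (3 and 1), with DNAJB1 up by 0.65 (SE 0.11), and the test pointed up with a median of -0.02, lost at adjusted p = 0.936 with an estimated correlation. CXCL3, a chemokine, fell by 2.58 (SE 0.40), NFKBIA fell by 1.30 (SE 0.22) and GDF15, a stress cytokine, fell by 0.87 (SE 0.14). Ribosomal protein and proteasome lists had 2 members lower (2 and 2 over the list alone), respiratory chain, mitosis and globin lists 1 (0, 1 and 1), interferon genes 1 higher (1, with 2 lower), and glycolysis, cholesterol, mitochondrially encoded genes and lineage markers 0 (edgeR, with 1 higher and 1 lower lineage marker over the list alone). On the TMM scale, 3 stress response, 3 cholesterol, 2 pause release, 1 polymerase and Mediator and 1 mitosis genes were higher and none lower, and S phase genes turned to 2 higher and 1 lower. In all 1071 genes fell and 122 rose, against 291 and 213 on the TMM scale, which moved genes up by a median of 0.20, and 1759 fell with a term for the replicate 2 drug libraries. Without DMSO replicate 2 the falls numbered 277, and without DMSO replicates 1 and 2 the rises numbered 68 and 64. Of the 122 rises 14 were processed pseudogenes, uncertain as above.

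A-485 against DMSO asked which genes depend on CBP and p300. New RNA fell in part of the erythroid regulators and of the globin, heme and membrane genes, while labelled output as a whole stayed near the DMSO level. NFE2 (hg38 chromosome 12, from 54292111 to 54301121) fell by 5.50 on the log2 scale (SE 0.40, n = 2, adjusted p = 1.1e-38), MYB fell by 4.15 (SE 0.53). LMO2 fell by 3.64 (SE 0.60), KLF1 fell by 3.31 (SE 0.62), MYC fell by 3.14 (SE 0.45), GATA2 fell by 2.99 (SE 0.25) and TAL1 fell by 2.98 (SE 0.48). With 10 and 2 labelled counts each under A-485, MYB stood at -5.68 and -3.42 and KLF1 at -4.85 and -2.58 without A-485 replicates 1 and 2. Without replicate 2 MYC stood at -4.02 and TAL1 at -3.80, with 7 and 19 and with 7 and 18 counts, so these sizes are uncertain. HBG1 (hg38 chromosome 11, from 5248079 to 5249859) fell by 4.01 (SE 0.23) and its near copy HBG2 fell by 4.47 (SE 0.25). The ferritin chain FTL fell by 1.40 (SE 0.18) and FTH1 fell by 1.11 (SE 0.20). Erythroid regulators fell in 15 of 23 (17 adjusted over the list alone) and globin, heme and membrane genes in 13 of 20 (13 lower and 1 higher over the list alone), both at adjusted p = 0.00623 with an estimated correlation. Immediate early genes fell in 18 and rose in 1 of 35 (20 and 1; adjusted p = 0.0206 with an estimated correlation), where IER3 fell by 2.06 (SE 0.22) and IER2 fell by 1.08 (SE 0.19). Cholesterol genes fell in 4 of 23 (8; adjusted p = 0.0421 with an estimated correlation), where INSIG1 fell by 1.86 (SE 0.31), and p53 targets in 3 of 17 (5; adjusted p = 0.0493), where GADD45A fell by 3.97 (SE 0.50) and GDF15 fell by 2.04 (SE 0.29).

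Glycolysis genes fell in 4 of 17 with A-485 (4 adjusted over the list alone; lost at adjusted p = 0.103 with an estimated correlation). PKM, the pyruvate kinase, fell by 2.36 (SE 0.22, n = 2, adjusted p = 7.7e-24), HK1, a hexokinase, fell by 1.76 (SE 0.34) and SLC2A3, a glucose transporter, fell by 2.34 (SE 0.43) and stood at -3.02 without A-485 replicate 1. Epithelial keratins that K562 cells express fell as well, with 3 of 5 lineage markers lower (3; adjusted p = 0.0421 with an estimated correlation), where KRT8 fell by 2.49 (SE 0.47) and KRT18 fell by 2.52 (SE 0.47) and stood at -1.93 and -3.56 without A-485 replicates 1 and 2. The chaperone HSPB1 fell by 1.41 (SE 0.21) and ZFP36L2, which promotes mRNA decay, fell by 1.41 (SE 0.25). Ribosomal protein genes lay above other genes as a set, with a median of 0.22 (0.35 on the TMM scale), 1 of 76 called higher, 0 over the list alone, and adjusted p = 0.0421 with an estimated correlation. S phase genes did too, with a median of 0.30, 1 of 42 higher, 0 over the list alone, and adjusted p = 0.0223. Few members fell in NF-kB (3 of 13; 3), stress response (4 of 22; 4), decay factor (3 of 56; 3), apoptosis (2 of 17; 3), histone (2 of 12; 2), heat shock (2 of 24; 2), pause release (1 of 25; 1) and MYC target lists (1 of 47; 1), and none of these held as a set with an estimated correlation. Respiratory chain, mitochondrially encoded, proteasome, polymerase and Mediator, mitosis and interferon lists had 0 called over all genes and over the list alone (edgeR). SRSF6, a splicing factor, rose by 0.93 (SE 0.19). In all 389 genes fell and 13 rose, against 333 and 27 on the TMM scale, which moved genes up by a median of 0.13. The rises numbered 57 in a fit of the 2 groups alone and 8 with a term for the replicate 2 drug libraries. Falls numbered 191 and 192 without DMSO replicates 1 and 2 and 217 and 198 without A-485 replicates 1 and 2, and rises 4, 2, 4 and 1 in the same order.

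Total RNA with A-485 fell in immediate early and short-lived mRNAs and in part of the erythroid regulators. MYC fell by 2.04 (SE 0.19, n = 2, adjusted p = 1.3e-09), ID2, an inhibitor of differentiation, fell by 2.87 (SE 0.17). JUN fell by 1.53 (SE 0.22), GATA2 fell by 1.42 (SE 0.11), NFE2 fell by 1.38 (SE 0.11) and KLF1 fell by 0.77 (SE 0.12). Immediate early genes fell in 17 of 39 (26 lower and 1 higher adjusted over the list alone; adjusted p = 0.00864 with an estimated correlation). Erythroid regulators fell in 12 of 28 (14), a set call lost at adjusted p = 0.0547 with an estimated correlation, and globin, heme and membrane genes had 0 of 38 called. GADD45A fell by 2.12 (SE 0.20) and GDF15 fell by 1.25 (SE 0.14) among 4 of 25 p53 targets lower (5), PPP1R15A, a stress phosphatase subunit, fell by 1.39 (SE 0.17) among 4 of 25 stress response genes (6). Falls also came in 3 of 25 cholesterol genes (4), 3 of 20 NF-kB genes (5), 3 of 26 apoptosis regulators (3), 3 of 62 decay factors (5), and 1 each of glycolysis, heat shock and interferon genes (1, 1 and 1). These calls as sets were lost with an estimated correlation, with adjusted p = 0.0967 for p53 targets, 0.0739 for NF-kB, 0.192 for the stress response, 0.310 for cholesterol and 0.414 for apoptosis. The remaining lists also had 0 members called over all genes (edgeR), and over the list alone 1 lineage marker was lower. BRD2 stood at 0.05 (SE 0.10) and HBG1 at -0.11 (SE 0.11), neither past the test. In all 175 genes fell and 5 rose (198 higher at an unadjusted p under 0.05). A fit of the 2 groups alone gave 290 and 24, a term for the replicate 2 drug libraries 275 and 9, and the TMM scale 153 and 12. Falls numbered 71 without DMSO replicate 2, 104 without A-485 replicate 1 and 82 without replicate 2, and rises 1, 3, 0 and 2 without DMSO replicates 1 and 2 and A-485 replicates 1 and 2.

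**Figure D3:**
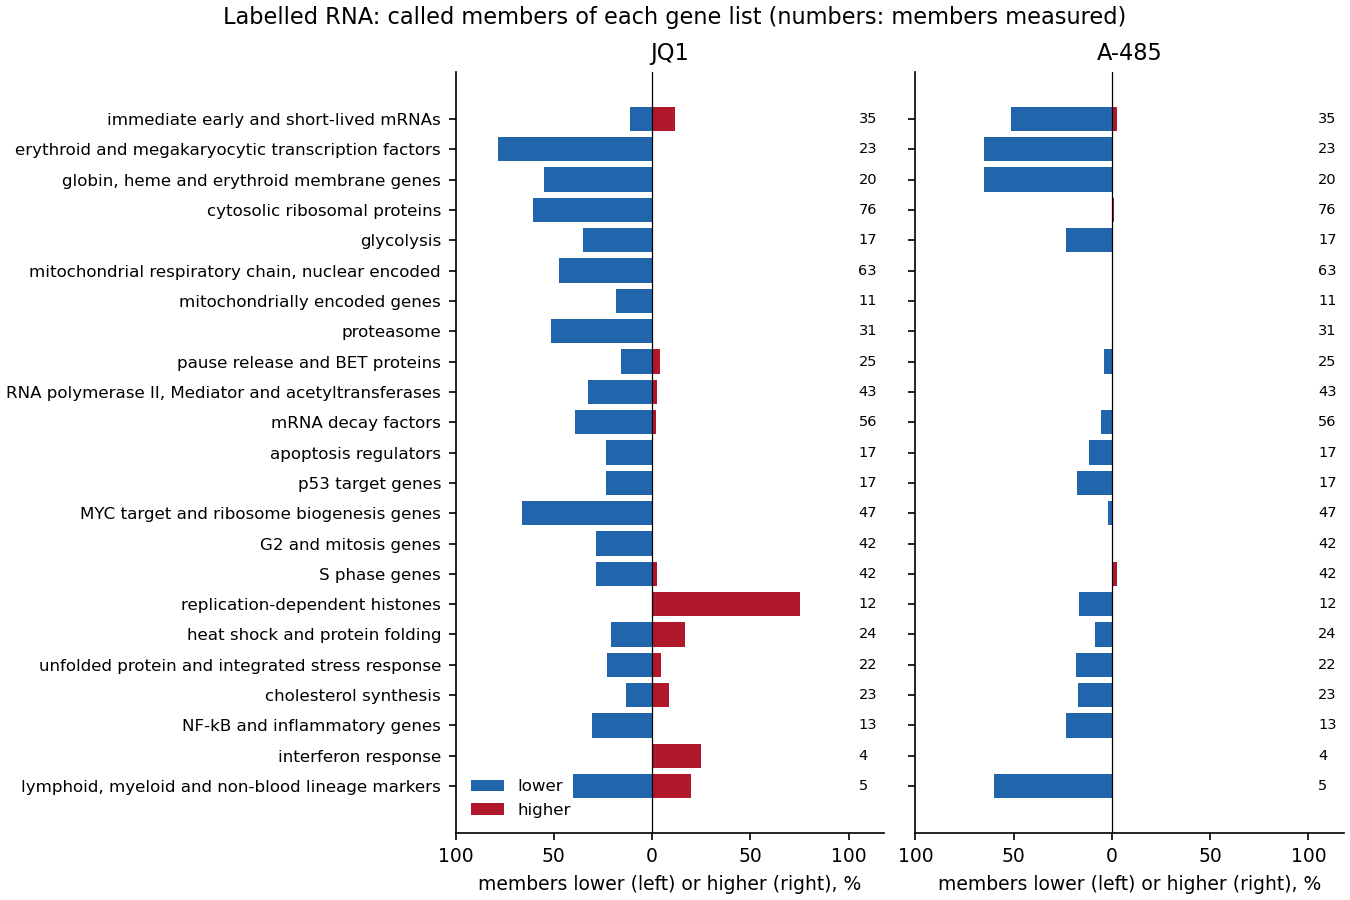
Percent of the measured members of each gene list called lower (blue, left) or higher (red, right) in labelled RNA under JQ1 and A-485 against DMSO, with the number of members measured at the right. Of 12 histone genes 9 were higher with JQ1 and 2 lower with A-485, and of 23 erythroid regulators 18 and 15 were lower.

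Neighbouring drugs were compared directly in labelled RNA. AZ-5576 left more than actinomycin D in 1639 genes and less in 0 (edgeR, 3 at an unadjusted p under 0.05, 0 with DESeq2), against 647 and 7 on the TMM scale. CUX1, a homeobox factor, held 189 and 257 labelled counts against 0 and 0, and BCYRN1, a small RNA made by RNA polymerase III, 269 and 271 against 0 and 0. The higher count was 975 without actinomycin D replicate 1 and 877 without replicate 2. JQ1 left more than AZ-5576 in 6791 genes and less in 31, against 2841 and 400 on the TMM scale, which moved genes down, by a median of -2.14. ANK1 was lower with JQ1 than with AZ-5576 by a log2 value of -1.62 (SE 0.25, n = 2, adjusted p = 4.9e-10) and ZMYND8, a chromatin reader, by -2.12 (SE 0.31). A-485 left more than JQ1 in 1984 genes and less in 251, against 491 and 606 on the TMM scale, which moved genes by a median of -0.64. H2BC21 was lower with A-485 than with JQ1 by a log2 value of -4.42 (SE 0.61), H4C15 by -4.31 (SE 0.54) and GADD45A by -3.93 (SE 0.50), while MRPL3, a mitochondrial ribosomal protein, was higher by 3.96 (SE 0.55). The sizes for H2BC21 and H4C15 are uncertain, with 0 and 7 and with 10 and 1 labelled counts under A-485. Without A-485 replicate 1 H4C15 stood at -6.64 and H2BC21 at -3.45, and without replicate 2 H4C15 stood at -3.45 and H2BC21 had no counts left with A-485. MRPL3 stood at 3.26 and 5.26 without JQ1 replicates 1 and 2. The higher count was 1234 without JQ1 replicate 2 and 1241 and 889 without A-485 replicates 1 and 2, and the lower count was 166 and 167 without JQ1 replicates 1 and 2 and 155 and 143 without A-485 replicates 1 and 2.

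The labelled share of each gene, its labelled over its unlabelled reads, needs no spike-in. With JQ1 the share of MYB fell by 2.68 on the log2 scale (SE 0.45, n = 2, adjusted p = 9.6e-06) and that of HBG1 fell by 2.64 (SE 0.22), and with A-485 they fell by 3.75 (SE 0.51) and fell by 3.95 (SE 0.24). The share of MYB stood at -3.29 without JQ1 replicate 1, and at -5.22 and -3.04 without A-485 replicates 1 and 2. NFE2 fell by 2.12 (SE 0.41) with JQ1 and fell by 4.27 (SE 0.52) with A-485. MYC, whose total RNA fell with its labelled RNA, stood at -0.80 (SE 0.66) with JQ1 and -1.36 (SE 0.68) with A-485 and passed no test. Across 7960 genes the share fell in 7849 with actinomycin D, 7454 with AZ-5576, 1225 with JQ1 and 210 with A-485, and rose in 1, 4, 29 and 2. RPL31P49, a processed pseudogene, was the 1 gene higher with actinomycin D. The counts for JQ1 and A-485 also depended on the tool, since limma on the log2 ratio gave 459 lower and 12 higher and 50 and 1. Relative to the typical gene, limma with the median ratio of each library subtracted gave 943 lower and 385 higher, 992 and 1029, 51 and 9, and 32 and 1, having moved genes up by a median of 7.57, 5.04, 0.69 and 0.10. With actinomycin D and AZ-5576 the typical gene had labelled counts at or near 0. Its ratio there may follow the 0.5 added to each count, so the centred counts for these drugs are not read. The falls with JQ1 numbered 309 and 449 without DMSO replicates 1 and 2 and 673 without JQ1 replicate 2, and its rises 5, 5, 6 and 13 without DMSO replicates 1 and 2 and JQ1 replicates 1 and 2. With A-485 the falls numbered 63, 83, 102 and 115 and the rises 1, 0, 0 and 0 in the same order, and with AZ-5576 the rises were 2 without either of its libraries.

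The mRNAs that ran down in total RNA were those with a high labelled share in DMSO, which marks fast turnover. Across 10409 genes, which are not independent replicates, the log2 change in total RNA and the labelled share in DMSO had a Spearman rho of -0.636 with actinomycin D, -0.567 with AZ-5576, -0.263 with JQ1 and -0.0417 with A-485, 4 relations in all. From the lowest to the highest bin of labelled share, with medians of 0.806% and 13.3%, the median mRNA left went from 97.4% to 62.4% of DMSO with actinomycin D, from 102% to 67.9% with AZ-5576, from 90.9% to 79.0% with JQ1 and from 97.6% to 95.1% with A-485. When the share came from 1 DMSO library and the change was taken against the other, rho was -0.567, -0.511 and -0.229 for the first 3 drugs. Each is the mean of both ways to divide the DMSO libraries. With A-485 the relation changed sign between libraries, as rho was 0.0159 for replicate 1 against DMSO replicate 1 and -0.0978 for replicate 2 against DMSO replicate 2.

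**Figure D4:**
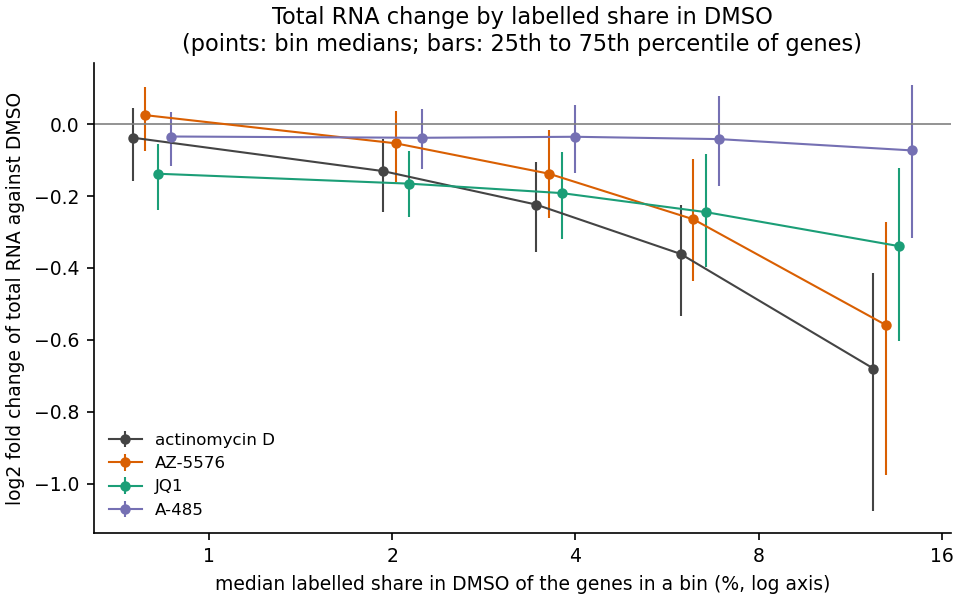
Median log2 change in total RNA in 5 bins of labelled share in DMSO for each drug, with the interquartile range of genes and about 2082 genes per bin. The line falls from -0.04 to -0.68 with actinomycin D and stays between -0.03 and -0.07 with A-485.

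Drug responses were compared with each other across genes. In total RNA, actinomycin D and AZ-5576 shared 1531 genes lower where independent calls would share 370, and AZ-5576 and A-485 shared 145 against 22.6. MYC, NFE2 and GATA2 were lower in total RNA with all 4 drugs. In labelled RNA JQ1 and A-485 shared 241 genes lower against 111 for independent calls, including NFE2, MYB, LMO2, HBG1 and HBG2. All drugs share the DMSO libraries, so chance alone gives a positive relation between them. Simulated sets that shared DMSO and nothing else had a covariance of log2 changes of 0.157 in labelled RNA and 0.0714 in total RNA. The measured covariance in labelled RNA was 0.401 for AZ-5576 and JQ1, 0.310 for JQ1 and A-485 and 0.148 for AZ-5576 and A-485, and in total RNA 0.314 for actinomycin D and AZ-5576 and 0.0939 for AZ-5576 and A-485. Pearson r was 0.505 in the simulated sets of either table and lower for these pairs (0.233, 0.337, 0.105 and 0.30) but for actinomycin D and AZ-5576 in total RNA (0.635). A lower r cannot decide whether a response is shared, since changes particular to 1 drug also lower r. By covariance in labelled RNA, JQ1 and A-485 lay above the simulated sets. AZ-5576 lay above them with JQ1 and near them with A-485, but the simulated drugs had DMSO levels. With AZ-5576 a mean of 648 genes had at least 10 labelled counts, against 7223.5 in DMSO. The simulated sets therefore cannot decide on the pairs with AZ-5576 in labelled RNA. No excess was tested, so whether the shared counts reflect shared responses stays open. For actinomycin D and AZ-5576 in labelled RNA the covariance was 0.845, which is not read as a shared response, since changes near 0 counts follow the DMSO counts. The DMSO libraries were not divided between the drugs, so the common controls can add to each shared count.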

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

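The comparison of JQ1 with A-485 was set before the data were examined, while the tests of labelled RNA in pseudogenes, of agreement between replicates and of the labelled counts left under actinomycin D, and the use of actinomycin D to compare gene lengths, were chosen only after the result was seen. A set of 16 results stood out because JQ1 and A-485 moved the same gene in opposite directions against DMSO, both past the threshold and past it in the difference between the drugs (edgeR, n = 2 libraries per group), and 14 of them are given here. The difference follows from that choice and adds no support, so its size is given without a p-value. In labelled RNA, IER5, an immediate early gene, stood at 0.97 with JQ1 and -1.11 with A-485 on the log2 scale, a difference of -2.08 (SE 0.23), and lost its A-485 call without A-485 replicate 1 (adjusted p = 0.0822). MIDN, a nuclear protein that promotes degradation of immediate early proteins, differed by -2.84 (SE 0.25). The histone genes H2BC21 and H3C10 differed by -4.42 (SE 0.61, and -3.45 without A-485 replicate 1) and -3.66 (SE 0.44), and INSIG1, a brake on cholesterol synthesis, by -2.67 (SE 0.30). DYNLL1, a dynein light chain, differed by -1.31 (SE 0.21), and HSPA1A, a heat shock gene with a near-identical copy that makes it uncertain, by -1.60 (SE 0.21). In total RNA, IER5 stood at 1.17 and -0.89, a difference of -2.06 (SE 0.12), MIDN differed by -1.61 (SE 0.10), IER2 by -1.17 (SE 0.13) and DNAJB1 by -1.13 (SE 0.11). TNFSF9, a cytokine, differed by -1.76 (SE 0.22), TXNIP, an inhibitor of glucose uptake, by -1.35 (SE 0.14), and the readthrough transcript PPAN-P2RY11 by 1.42 (SE 0.20). No technical explanation of these was tested.

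Several of these opposite calls rest on single libraries. In labelled RNA with A-485, H3C10 was lost without DMSO replicate 2 or either A-485 library (adjusted p = 0.531, 0.114 and 0.0571), H2BC21 without DMSO replicate 1 or A-485 replicate 1 (with 0 and 7 counts under A-485, 0.555 and 0.594, and 0.806 in DESeq2 with all libraries), and HSPA1A without the same libraries (0.478 and 0.383). With JQ1, INSIG1 was lost without DMSO replicate 2 or JQ1 replicate 1 (0.278 and 0.0754) and HSPA1A without DMSO replicate 2 (0.0661). In total RNA, DNAJB1 and PPAN-P2RY11 lost the A-485 call without any 1 of the 4 libraries compared (DNAJB1 0.0851, 0.265, 0.204 and 0.388, PPAN-P2RY11 0.546, 0.0918, 0.206 and 0.388 without DMSO replicates 1 and 2 and A-485 replicates 1 and 2). IER2 was lost with JQ1 without DMSO replicate 2 or JQ1 replicate 1 (0.223 and 0.148) and with A-485 without DMSO replicate 1 or A-485 replicate 2 (0.0980 and 0.0759). DESeq2 also did not call the H2BC21 difference between JQ1 and A-485 (adjusted p = 0.0998) or PPAN-P2RY11 with A-485 (0.0635).

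Under AZ-5576, 59 protein-coding genes above 200 kb kept as a pool 35.2% of the labelled RNA of DMSO, against 4.44% over 1420 genes under 50 kb. The ratio was 7.93 (bootstrap interval 5.22 to 11.1, drawn over genes and not libraries). CUX1 kept 124% and ANK1 94.4%, both of which overlap another gene on the same strand. Length was the annotated span of a gene, so HBG2 counted as long at 252.4 kb. It had 850 and 762 labelled DMSO counts and kept 5.69%. Most long genes still fell: 7 of the 59 were not called lower, the median log2 change was -2.18, RUNX1 and DLC1 had 0 and 0 counts, and Spearman rho of the level left with length was 0.151 over 1928 genes. Low counts are argued against by genes with at least 200 labelled DMSO counts, which gave 8.60 (4.56 to 14.1, 15 long genes), and overlapping genes by genes without one on the same strand, which gave 8.32 (4.39 to 11.8, 16 long genes). Whether polymerases past the pause site when CDK9 was inhibited went on through long genes stays open, since actinomycin D, which stops elongation, gave a ratio of 0.455 (0.169 to 1.12) from too few counts to decide, with 0.0874% left in long and 0.192% in short genes. Priming inside introns was not tested and stays open.

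Of 419 processed pseudogenes measured in total RNA under actinomycin D, 11 were 2-fold or more higher and 39 2-fold or more lower, against 0 higher and 480 lower of 9146 protein-coding genes, and RPL34P6 went from 136 and 103 counts to 1692 and 1849. With AZ-5576 and JQ1 7 each were 2-fold or more higher, and RPL34P6 had 981 and 1075 counts and 1109 and 988. With A-485, of 440 measured, 0 were 2-fold or more higher and 0 lower, and RPL34P6 had 134 and 117 counts. Synthesis in the label hour is argued against by a labelled share of 0.00424% in these pseudogenes, which says nothing of the hour before, and few counts by a correlation of 0.846 between replicates across pseudogenes. Among RNAs with a low labelled share, log2 changes of pseudogenes had an SD 3.66 times that of matched protein-coding genes under actinomycin D. Reads divided differently between near-identical copies may therefore explain the higher counts. With AZ-5576 and JQ1 the SD was 1.93 and 1.28 times that of matched genes, so this is less clear there. With A-485 it was 1.17 times. RPL12P19 moved the other way under actinomycin D, from 213 and 234 counts to 8 and 13. No other biological explanation was tested.

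Labelled counts did not reach 0 under actinomycin D, with 3024 left. Of these, 26.0% lay in 71 genes with a labelled share above 10%, of which 54 were processed pseudogenes, and the median ratio of their share in DMSO to that under actinomycin D was 1. RPL31P49 alone held 364 of the 785 counts in these genes, and without it, a check added after the 26.0% was seen, 15.8% were left. Whether fixed sequence differences read as conversions account for the labelled counts left therefore stays open. An error rate equal for all transcripts is argued against by a chi-square per degree of freedom of 39.8, of which RPL38 made up 86.5%, and of 5.54 without it, a check also added later. The source of the other labelled counts stays open.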

How the results depend on the processing

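Tests with a term for the replicate 2 drug libraries, without processed pseudogenes and without mitochondrial genes were chosen only after the result was seen, and the other alternatives were planned. For named genes, 9126 values under an alternative kept their side of the threshold, 912 kept the direction and lost the call, and 15 gained a call. A further 35 changed direction and were called in either fit. Values that changed direction with no call in either fit are among the 9126. DESeq2, TMM factors of the total table and median-of-ratios spike-in factors moved no count of genes beyond 1.5 times.

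TMM factors of the human counts aim to set the typical gene to no change, which moves genes between higher and lower. In labelled RNA the median gene came to -0.08 with JQ1 and 0.04 with A-485. It stayed at -6.68 with actinomycin D and -3.43 with AZ-5576, and at 3.28 for JQ1 against AZ-5576. Counts in these comparisons are therefore not relative to a typical gene without change. TMM factors gave 25 higher and 2268 lower in labelled RNA with actinomycin D, 392 and 3111 with AZ-5576, 401 and 471 with JQ1 and 27 higher with A-485. Between drugs they gave 647 higher and 7 lower for AZ-5576 against actinomycin D, 2841 and 400 for JQ1 against AZ-5576, and 491 and 606 for A-485 against JQ1. In total RNA they gave 836 and 1142 with actinomycin D, 517 and 1210 with AZ-5576, 213 and 291 with JQ1 and 12 higher with A-485. Changes of direction are listed only for named genes called in either fit. Genes that changed direction in labelled RNA with AZ-5576 were MT-ND4 (2.76), MT-ND1 (2.76), MT-CYB (2.67), MT-ATP6 (2.46), GATA2 (1.23), UQCRH (0.45), PSMB1 (0.41), RPL32 (0.21), BCL2L1 (0.10) and IER2 (0.067). With JQ1 they were GAPDH (0.63), ACTB (0.59), MT-CYB (0.38), MT-ATP6 (0.27), LDHA (0.25), RPL15 (0.25), TAF1D (0.14), ATP5MC3 (0.062), LSM1 (0.020), LDHB (0.014) and ID2 (0.0096), and in total RNA with actinomycin D MYB (0.25).

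With at least 50 counts in at least 2 libraries, fewer genes were tested, 2361 in labelled RNA. The counts were 2360 lower with actinomycin D, 0 higher and 2336 lower with AZ-5576 (16 higher in the edgeR fit of all genes), 1280 lower with JQ1, 1089 higher and 1 lower for AZ-5576 against actinomycin D, 2247 higher and 7 lower for JQ1 against AZ-5576, 1165 higher for A-485 against JQ1, and 75 higher in total RNA with AZ-5576. For the share, 50 labelled and 50 unlabelled counts gave 2350 lower with actinomycin D, 1 higher and 2320 lower with AZ-5576 and 8 higher with A-485. With no filter the counts were 3 higher in labelled RNA and 8 higher in total RNA with A-485, and 11 higher in the share with JQ1, and the cause was not tested.

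Fits of the 2 groups alone gave 57 higher with A-485 in labelled RNA, 408 higher of 418 tested for AZ-5576 against actinomycin D, 4506 higher of 4884 for JQ1 against AZ-5576, and 24 higher and 290 lower with A-485 in total RNA. Replicate numbers were not taken as pairs, since the correlation between groups of the difference between replicates 1 and 2 was not over 0.1 in each comparison. It ran from -0.103 to 0.373 over 10 comparisons of groups in total RNA and from 0.0364 to 0.0955 over 3 in labelled RNA. With values up to 0.373, and with replicate 2 drug libraries that stood apart in the spike-in counts (below), structure shared by replicate number is not excluded. A replicate block, used as an alternative, gave 1972 lower with JQ1 and 13 higher with A-485 in total RNA, and 0 higher in the share with A-485 (edgeR, 152 at an unadjusted p under 0.05 without that term). A term for the replicate 2 drug libraries gave 1759 lower with JQ1, 9 higher and 275 lower with A-485 in total RNA, 8 higher with A-485 in labelled RNA, and 16 and 1 higher in the share with JQ1 and A-485. Without processed pseudogenes 26 genes were higher in total RNA with actinomycin D. Where fewer genes tested does not account for these values, the cause was not tested.

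For the share, limma gave 2 higher with actinomycin D, 12 higher and 459 lower with JQ1, and 1 higher and 50 lower with A-485. With the median ratio of each library subtracted, which centres the typical gene, it gave 385 and 943, 1029 and 992, 9 and 51, and 1 and 32 in the order of the drugs. Shares of genes called in either fit that changed direction were IER2 (2.21), MYC (1.93), JUN (1.39), TFRC (1.35), BCL2L1 (1.25), BRD2 (1.25), LMO2 (0.82), NFE2 (0.73), MYB (0.62), ACTB (0.48), GATA1 (0.41) and MCL1 (0.18) with AZ-5576 and JUN (0.052) with actinomycin D. With these drugs the typical gene had labelled counts at or near 0, so the centre may follow the 0.5 added to each count. JUN had 0 and 0 labelled counts with actinomycin D. The MYC share was 4.81% with AZ-5576 against 24.8% in DMSO. The centred counts and directions for these drugs are therefore not read as rises.

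The median labelled share over genes with at least 50 total counts was 3.35% in DMSO, 0.0% with actinomycin D, 0.0% with AZ-5576 and 3.02% with A-485. Without the 10 genes with the most counts the labelled share was 0.00923% with actinomycin D and 0.246% with AZ-5576, the total ratio to the spike-in was 7.80, 7.18, 7.53, 7.08 and 7.64 from DMSO to A-485, and labelled counts per 1000 spike-in counts were 220.4, 0.662, 18.5, 139.9 and 200.8. Without mitochondrial genes the share was 0.00862% and 0.172%, the total ratio 7.46, 7.76, 7.30 and 7.87 for the drugs, and labelled counts per 1000 were 215.7, 0.643, 13.3, 135.6 and 197.6 from DMSO on. These values differ because genes were left out.

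The relation of total change to labelled share had rho -0.567, -0.511 and -0.229 for actinomycin D, AZ-5576 and JQ1 with the DMSO libraries divided, which removes noise shared between both sides, and -0.614 and -0.275 for AZ-5576 and JQ1 with at least 200 total counts. Among genes with at least 50 labelled DMSO counts, Pearson r between labelled responses was 0.0108 for actinomycin D and AZ-5576, -0.0812 for actinomycin D and JQ1, 0.0379 for actinomycin D and A-485, 0.0961 for AZ-5576 and JQ1 and -0.0371 for AZ-5576 and A-485, and the cause was not tested. No simulated value was made for these genes, so none of these r is read as a shared response.

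Leaving out a library leaves a group with 1 library, assumed to vary like the other groups. In labelled RNA the counts then ran from 5 to 11 higher with AZ-5576, 51 to 61 higher and 1049 to 1675 lower with JQ1, 1 to 4 higher and 191 to 217 lower with A-485, 877 to 1597 higher for AZ-5576 against actinomycin D, and 889 to 1441 higher and 143 to 167 lower for A-485 against JQ1. In total RNA they ran from 27 to 47 higher and 1205 to 2725 lower with actinomycin D, 44 to 68 and 903 to 1626 with AZ-5576, 64 to 129 and 277 to 973 with JQ1, and 0 to 3 and 71 to 138 with A-485. For the share they ran from 2 to 6 higher with AZ-5576, 5 to 13 higher and 309 to 981 lower with JQ1, and 0 to 1 higher and 63 to 115 lower with A-485. In data simulated for A-485 against DMSO alone, the labelled fit recovered 21% of 2-fold changes and the total fit 73%, so small changes in labelled RNA were often not detectable there, and the other drugs were not simulated.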

Other observations

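No hypothesis beyond the patterns above was tested, and the grouping of libraries by spike-in counts was examined only after the data were seen. Across 2387 Drosophila genes with a mean of at least 100 counts, 210 ways to divide the 10 libraries into sets of 4 and 6 were compared. The replicate 2 libraries of the 4 drugs were separated from the other 6 by 145 genes, against 56 for the next highest division and a median of 21. The first component of the spike-in counts held 22.2% of the variance and the second 12.5%. RPL31P49, a processed pseudogene, had labelled counts of 144 and 220 under actinomycin D and 196 and 192 in DMSO.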
